A study of Mus musculus with 6 samples.

How the data were processed

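Poly-A selected RNA of cultured mouse brain astrocytes was sequenced as 6 bulk libraries, 3 from wild-type cells (WT) and 3 from cells lacking ADGRB1 (KO), an adhesion G protein-coupled receptor of the brain. Libraries were made with a NEBNext Ultra II kit and read as paired ends, per the labels' protocols. The deposited table holds estimated counts per gene symbol for each library, not normalized by the authors. Alignment with TopHat2 and counting with featureCounts are named in the submitters' processing notes, without versions, and so are the genome builds GRCm38 and mm9, without their roles. The annotation that was counted, the handling of reads that match several genes and the use of strand are not given in the sources used here, so genes with an overlapping neighbour are named as uncertain. Nearly all values were whole numbers. Between 0.711% and 0.847% of the values per library lay more than 0.01 from a whole number, and all values were rounded to whole numbers before testing. Reads shared between genes can be split among them in such a table, which affects close gene copies most.

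Libraries were grouped by the genotype in the labels, and each column of the table was matched to a library by its name. The labels do not say whether the 3 libraries of a group came from separate cultures or animals, so p-values measure the spread between these libraries, which may be partly technical. Replicates of a group were compared before averaging. Their counts differed far beyond sampling noise, with a chi-square of 22.3 to 89.1 per degree of freedom over genes with a summed count of at least 10, so no library was counted as a duplicate. The 6 libraries held 17460086 to 20334440 counts each.

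The table has 24318 gene symbols, of which 23905 (98.3%) matched a gene of GENCODE release M21 (GRCm38) by name or through RefSeq symbols and synonyms. Coordinates, GC content and exonic length are from that annotation on GRCm38 and are not the authors' coordinates. After filterByExpr removed genes with low counts, 14131 genes were tested.

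KO was compared with WT by the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM normalization, robust dispersion estimates and Benjamini-Hochberg adjustment at an adjusted p of 0.05. Levels are given as CPM scaled by TMM with the SD over 3 libraries, and log2 fold changes are KO over WT with their standard error (SE). Log2 CPM used a prior count of 2. A fold against a group whose libraries all hold 0 counts was computed against a floor of 3 counts over the group, which covers counting error only. The test was tried on simulated data for this comparison, drawn for 14131 genes from the measured means, dispersion trend and library sizes with 200 changed genes in each of 5 simulations. It recovered 9.34% of the genes changed 1.5-fold, 44.9% of those changed 2-fold and 88.6% of those changed 4-fold. A simulated list of 15 genes lowered 2-fold was called in 5 of 5 simulations. Genes were drawn independently there, so the simulation says nothing about lists whose genes vary together between libraries.

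Before the data were examined, 40 gene lists were fixed that cover engulfment, astrocyte functions and states, general cell processes and markers of other cell types that a culture can hold. Lists with at least 3 tested members were compared with all other genes by camera of limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 39 lists tested. Each member was also called with p-values adjusted over the list alone. The named genes were fixed by rule at the same time. The rule takes Adgrb1, Adgrb2, Adgrb3, Megf10, Mertk, Gfap, Aqp4 and Slc1a2 in any case, then called genes by size and by p among those of at least 2 CPM whose groups do not overlap, without predicted or unnamed genes, and up to 4 called members per direction of each list. For a direction with under 5 called genes it takes the 10 genes of smallest unadjusted p as values, not as changes. Members of a list were taken as called when their p adjusted over the list alone passed the threshold. Genes singled out after their values were seen are said to be so. A member of the mature oligodendrocyte list enters its counts and tests but is not reported by name here.

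The alternatives fixed in advance were RLE normalization, total counts, no low-count filter, a filter of at least 1 CPM in 3 libraries, the Wald test of DESeq2 1.42.0, limma voom with sample quality weights, the replicate number as a block, a fold change of at least 2, leaving out each library in turn, and, for lists, camera with an estimated correlation and fry. Others were added after the libraries were seen to differ in a trend with GC content and gene length: the removal of that trend per library by natural splines with 4 degrees of freedom, the side of the trend as a batch term, and 1 surrogate variable from sva 3.50.0. The bias-adjusted quasi-likelihood of edgeR and a dispersion estimated without robust steps were added too, the latter with the quasi-likelihood step still robust. Figures were drawn with matplotlib 3.10.9.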

Results

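Gene expression was measured by poly-A RNA sequencing in cultured mouse astrocytes, the glial cells that support neurons and engulf synaptic material, in 3 WT and 3 KO libraries. WT libraries held 17460086 to 18897340 counts and KO libraries 19251608 to 20334440. The design asks which genes change in astrocytes when ADGRB1, a receptor that takes part in engulfment, is lost.

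Adgrb1 itself fell in KO, to 138 ± 20.3 CPM (SD, n = 3) from 327 ± 33.1 CPM in WT (n = 3), so that 42.3% of the WT level remained. The gene lies on chromosome 15 at 74516195 to 74589465 (GRCm38, plus strand). The 3 KO libraries held 158, 140 and 117 CPM and the 3 WT libraries 299, 363 and 317 CPM, and the direction matched the labels in 6 of 6 libraries. Its log2 fold change was -1.24 ± 0.16 (SE), with an edgeR quasi-likelihood p of 0.000116 adjusted over the 8 fixed genes alone and an adjusted p of 0.0684 over all genes tested. The labels do not say which part of the gene is deleted, and gene totals cannot show whether the remaining reads come from outside it.

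Genes of oligodendrocytes, the myelin-forming glia, were lower in KO, and their list had the smallest camera p of the 39 lists with all 6 libraries and the preset correlation. Of 15 markers of mature oligodendrocytes, 10 fell in KO when adjusted over the list alone, 0 rose and 5 did not pass, and over all genes tested 0 passed. Mal fell from 895 ± 208 to 427 ± 74.2 CPM (SD, n = 3 each), Cldn11, a tight junction protein of myelin, from 451 ± 113 to 226 ± 28.4 CPM, Mog from 162 ± 33.0 to 82.6 ± 16.2 CPM, and Mag from 491 ± 117 to 242 ± 50.4 CPM. Cnp, Ermn, Myrf, Opalin and Ugt8a were among the others. Cnp and Ermn have exons that overlap a gene on the opposite strand and are uncertain. The median log2 fold change of the list was -0.97, with a camera adjusted p of 4.35e-08. With an estimated correlation the list's adjusted p was 0.392, and with fry 0.126. Leaving out each library in turn, between 8 and 12 of the 15 genes fell. Among the single calls lost were Opalin without WT replicate 2 and Ugt8a without WT replicate 1 or KO replicate 2. Mbp and Mobp, singled out after their values were seen, did not go with the rest. Mbp, which encodes myelin basic protein, stood at 7442 ± 2926 CPM in WT and 10710 ± 1811 CPM in KO (log2 fold change 0.53 ± 0.29, SE), and Mobp at 832 ± 314 and 923 ± 110 CPM (0.15 ± 0.27). WT replicate 3 was lowest for both, and without it Mbp was at 0.25 and Mobp at -0.13, while Mbp was at 0.81 without WT replicate 1.

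**Figure D1:**
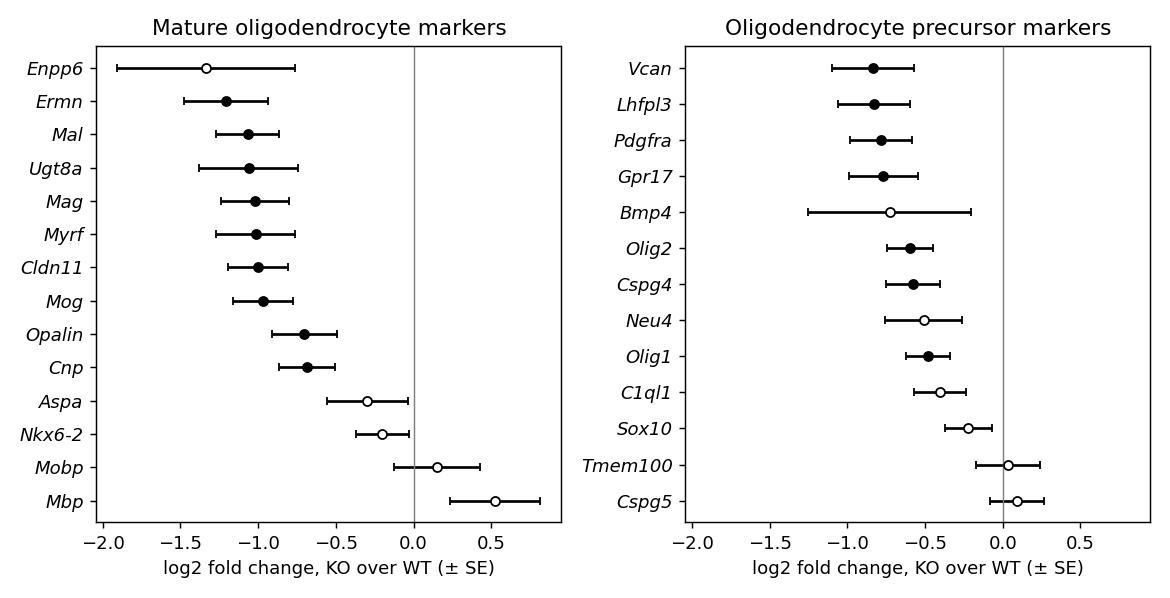
Log2 fold change of KO over WT for 14 of the mature oligodendrocyte markers and 13 oligodendrocyte precursor markers, as points with bars of 1 SE. Filled points passed the test adjusted over the list alone, 9 in the first panel and 7 in the second, all of them below 0, while Mbp and Mobp lie above 0.

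Oligodendrocyte precursor markers were lower as well. Of 13 genes, 7 fell when adjusted over the list alone and 6 did not pass. Pdgfra, the growth factor receptor of these precursors, fell from 574 ± 95.8 to 333 ± 73.4 CPM, Gpr17 from 542 ± 120 to 319 ± 80.0 CPM, Olig2 from 229 ± 13.6 to 152 ± 22.4 CPM, and Lhfpl3 from 93.7 ± 19.5 to 52.9 ± 14.7 CPM. Pdgfra overlaps Mir7025 on the same strand, Gpr17 overlaps Lims2 and Lhfpl3 overlaps A930003O13Rik on the opposite strand, so these genes are uncertain. The list's median was -0.58 (camera adjusted p = 1.74e-06), and its adjusted p was 0.392 with an estimated correlation. Without WT replicate 1, WT replicate 3 or KO replicate 2, 0 of these genes passed. Sox10, singled out after its values were seen, stood at 211 ± 12.6 CPM in WT and 181 ± 28.8 CPM in KO (log2 fold change -0.22 ± 0.15).

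Microglia and macrophage markers, a list of 25 genes for the brain's resident phagocytes, had a median log2 fold change of -0.35 with 23 of 25 genes below 0 (camera adjusted p = 8.22e-06). Its adjusted p was 0.558 with an estimated correlation, and 0 of the 25 genes passed when adjusted over the list alone. The list's mean in WT replicate 1 lay within the range of the KO libraries.

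Astrocyte genes stood slightly higher in KO. CPM are shares of each library, and the oligodendrocyte and microglia lists were lower. A shift in the share of cell types therefore cannot be told apart from a change within astrocytes. The same limit holds for the other marker lists. The 27 astrocyte identity genes had a median log2 fold change of 0.21, with 25 of them above 0 (camera adjusted p = 0.000133, and 0.392 with an estimated correlation), and 1 rose when adjusted over the list alone. That gene was Id3, at 138 ± 23.4 CPM in WT and 240 ± 48.4 CPM in KO, and it did not pass in this list without WT replicate 1, WT replicate 2 or KO replicate 1. Gfap, the intermediate filament of astrocytes that increases in reactive cells, was at 612 ± 36.7 CPM in WT and 1082 ± 457 CPM in KO, a log2 fold change of 0.82 ± 0.26 (edgeR adjusted p = 0.0487 over the 8 fixed genes alone and 0.650 over all genes tested). The KO libraries spread from 724 to 1596 CPM. The edgeR test of Gfap no longer passed without WT replicate 1 (adjusted p = 0.119 over the 8 genes), WT replicate 2 (0.163), WT replicate 3 (0.144), KO replicate 1 (0.125) or KO replicate 2 (0.0621), and without KO replicate 1 its log2 fold change was 0.42. It also missed the threshold over the 8 genes with total counts (adjusted p = 0.0657), a filter of 1 CPM (0.0519), the batch term for the GC trend (0.154) and 1 surrogate variable (0.0753, log2 fold change 0.47). Aqp4, the water channel of astrocyte endfeet, was at 746 ± 187 and 782 ± 258 CPM, and Slc1a2, the main glutamate transporter, at 9386 ± 1761 and 9083 ± 1014 CPM, and neither difference passed.

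**Figure D2:**
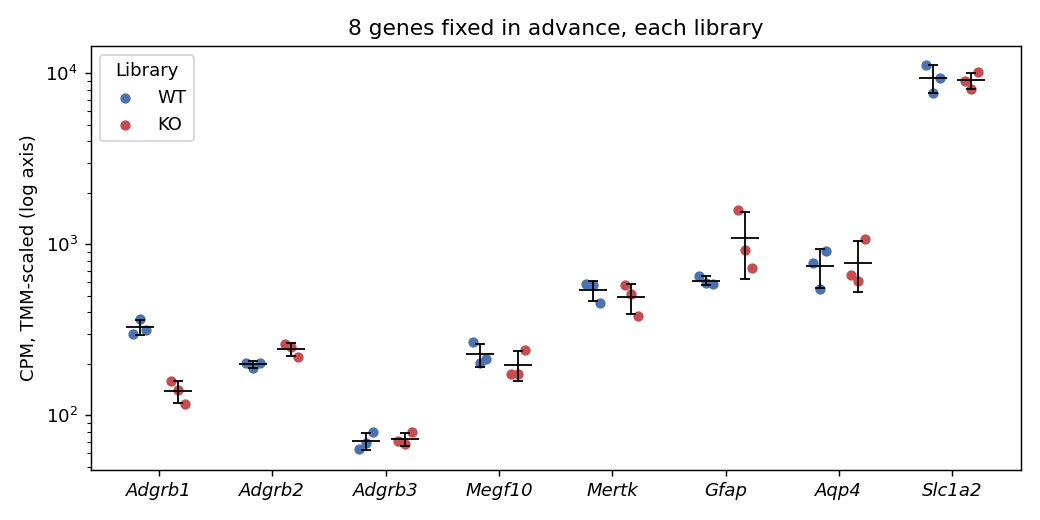
CPM scaled by TMM on a log axis for the 8 genes fixed in advance, with each point a library, blue for WT and red for KO, the horizontal dash the mean and the bars the SD over 3 libraries. Adgrb1 lies between 117 and 158 CPM in KO and between 299 and 363 CPM in WT.

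Transporters and Notch and BMP pathway genes held members that moved both ways. In the list of 20 tested genes for glutamate and GABA uptake and ion homeostasis, Slc6a11, a GABA transporter, rose from 1355 ± 64.1 to 2051 ± 156 CPM and Slc6a9, a glycine transporter, from 182 ± 16.8 to 273 ± 13.1 CPM, while Slc12a2, a sodium-potassium-chloride cotransporter, fell from 203 ± 24.9 to 97.5 ± 14.5 CPM, all adjusted over the list alone. Slc6a9 overlaps exons of B4galt2 and Ccdc24 on the opposite strand and is uncertain. The list's median was 0.17 (camera adjusted p = 0.0432, and 0.392 with an estimated correlation). Of 17 tested Notch and BMP targets, 4 rose and 1 fell when adjusted over the list alone. Hes5, a Notch target, rose from 140 ± 18.9 to 221 ± 10.4 CPM, and Heyl, another, from 24.0 ± 8.79 to 68.7 ± 29.4 CPM. Id3 and Bmp7 were the other genes that rose, and Smad7, an inhibitor of TGF-beta signalling, fell from 37.7 ± 2.56 to 25.8 ± 3.69 CPM. The list's median was 0.23 (camera adjusted p = 0.0119, and 0.392 with an estimated correlation). Of these single genes only Slc12a2 passed in its list in each of the 6 fits that left out a library. The cells of the culture that its reads came from were not told apart. Over all genes tested, 0 members of either list passed with all 6 libraries. Slc6a11 and Slc6a9 did not pass without WT replicate 1, WT replicate 3 or KO replicate 2. Of the Notch and BMP targets, 0 rose without WT replicate 1 or with a correction for GC content and length, and 2 without WT replicate 2 or 3, and Smad7 passed only without KO replicate 3. The camera adjusted p of the Notch and BMP list was 0.0601 without KO replicate 1 and 0.0571 without KO replicate 3, and that of the transporter list 0.236, 0.0744, 0.0629 and 0.161 without WT replicates 2 and 3 and KO replicates 1 and 3.

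Engulfment genes, the group closest to the study's title, did not pass as a list. Of 31 receptors and signalling genes 1 fell and 30 did not pass when adjusted over the list alone, with a median log2 fold change of -0.08 (camera adjusted p = 0.125). The gene that fell was Elmo1, which works with Dock proteins to activate Rac downstream of engulfment receptors, from 74.9 ± 7.57 to 42.2 ± 9.02 CPM, and it passed in 2 of the 6 fits that left out a library, not without WT replicate 1, 2 or 3 or KO replicate 1. The cells that its reads came from were not told apart, and the mature oligodendrocyte and microglia lists were lower too (medians -0.97 and -0.35). The fall of Elmo1 therefore cannot be placed in astrocytes. The phagocytic receptors Megf10 and Mertk did not pass, at 228 ± 35.2 and 198 ± 38.8 CPM and at 537 ± 74.1 and 490 ± 98.4 CPM in WT and KO. The related receptors were at 198 ± 8.40 CPM in WT and 243 ± 21.7 CPM in KO for Adgrb2 (log2 fold change 0.30 ± 0.13, adjusted p = 0.135 over the 8 fixed genes alone, but 0.0470 with limma voom and 0.0494 without KO replicate 3) and at 70.4 ± 8.11 and 72.7 ± 6.35 CPM for Adgrb3.

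Of the remaining lists past the threshold, oxidative phosphorylation (39 genes, median log2 fold change 0.26, camera adjusted p = 4.61e-07) and cytosolic ribosomal proteins (39 genes, median 0.26, camera adjusted p = 6.35e-07) were higher in KO with all 78 genes above 0. Their adjusted p was 0.575 and 0.590 with an estimated correlation, 0 of their genes passed when adjusted over the list alone, and WT replicate 2 lay above KO replicate 3 in both. Interferon response genes (34 tested, median 0.25), radial glia and neural progenitor markers (16 genes, median 0.21) and regional patterning genes (22 tested, median 0.24) were also higher, with camera adjusted p of 0.0119, 0.0137 and 0.0432, and of 0.558, 0.392 and 0.392 with an estimated correlation. When adjusted over the list alone, Hes5 rose among the radial glia markers (not without WT replicate 1 or KO replicate 2) and 0 genes passed in the interferon and patterning lists. The interferon list did not pass without WT replicate 1 (camera adjusted p = 0.0545) or KO replicate 3 (0.548), the radial glia list without WT replicate 2 (0.184) or KO replicate 3 (0.144), and the patterning list without WT replicate 2 (0.254), KO replicate 2 (0.0901) or KO replicate 3 (0.124). In all, 8 lists were higher and 3 lower of 39 tested, and 0 lists passed with an estimated correlation or with fry.

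**Figure D3:**
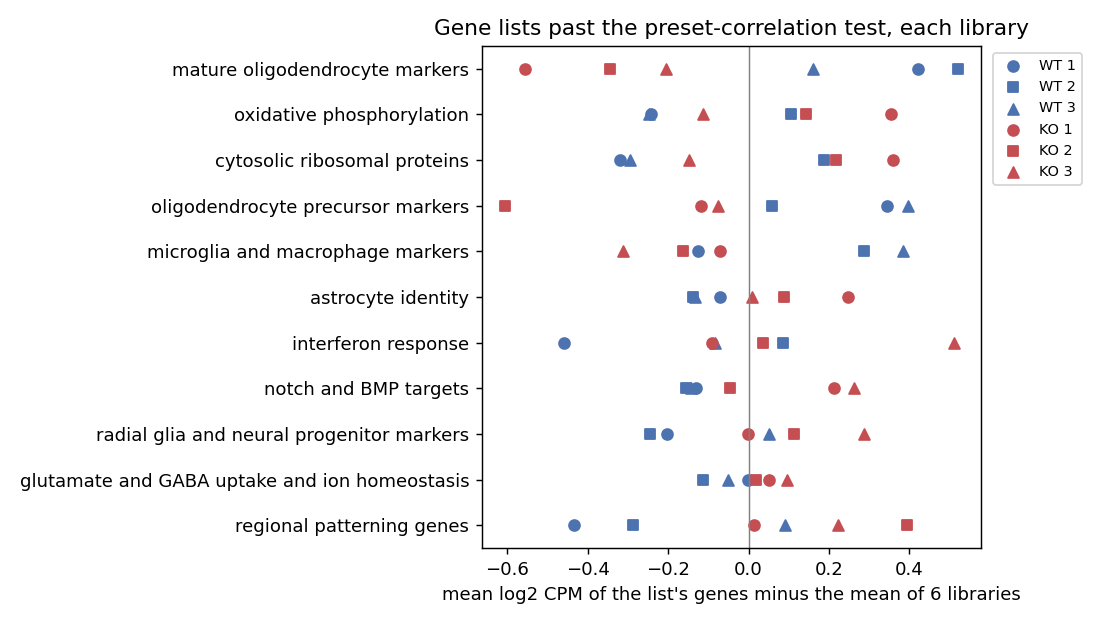
Mean log2 CPM of each list's genes minus the mean over 6 libraries, for the 11 lists past the camera test, with blue for WT, red for KO and a marker shape per replicate number. The 3 KO libraries lie below the 3 WT libraries for mature oligodendrocyte markers, and the genotypes overlap for oxidative phosphorylation and ribosomal proteins.

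No single gene passed over all genes tested in the main fit. With edgeR, 0 genes were higher and 0 lower in KO at an adjusted p of 0.05 over 14131 genes, and the smallest adjusted p was 0.0520. At an unadjusted p under 0.05 there were 871 genes, 330 higher and 541 lower, where 707 are expected by chance. DESeq2 called 17 genes higher and 62 lower, and limma voom with quality weights 2 and 6. Without KO replicate 3, 4 genes were higher and 27 lower. The counts were 7 and 37 with the replicate number as a block, 14 and 74 with the side of the GC trend as a batch term, and 28 and 65 with 1 surrogate variable. The values of 3 KO and 3 WT libraries did not overlap for 11.2% of genes, where chance gives 10%.

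The 10 genes of smallest p in each direction are given as values. Scube1, a secreted EGF-domain protein gene on chromosome 15 (83604999 to 83725021), stood at 6.38 ± 1.08 CPM in WT and 29.9 ± 6.56 CPM in KO (log2 fold change 2.23 ± 0.24, edgeR adjusted p = 0.0520). Gm5512, a transcribed pseudogene on chromosome 19 (12905320 to 12906841), rounded to 0 counts in the 3 WT libraries and held 6.87 ± 3.56 CPM in KO, at least 127-fold higher (adjusted p = 0.0684). As a pseudogene it can share reads with its parent gene and is uncertain. Gm28042 was at 3.33 ± 0.46 and 13.7 ± 6.14 CPM, and is uncertain because its exons overlap Jmjd7 and Pla2g4b on the same strand. The Wnt antagonist Sfrp5 was at 23.1 ± 5.53 and 53.5 ± 13.1 CPM, Igfbp5 at 290 ± 16.2 and 484 ± 62.4 CPM, the AMPA receptor subunit gene Gria1 at 80.5 ± 11.3 and 131 ± 6.55 CPM, Mpped1 at 23.1 ± 4.72 and 45.8 ± 9.10 CPM, and Mapk8ip2 at 28.4 ± 2.11 and 47.6 ± 7.01 CPM. Hes5 and Slc6a9 completed the 10 on the higher side.

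On the lower side, Slc24a2, a sodium-calcium exchanger gene, was at 64.8 ± 15.6 CPM in WT and 26.0 ± 1.82 CPM in KO (log2 fold change -1.32 ± 0.19, edgeR adjusted p = 0.153). Fa2h, which makes the hydroxylated fatty acids of myelin lipids, was at 86.4 ± 3.94 and 41.7 ± 8.22 CPM, Tspan2 at 326 ± 53.4 and 157 ± 21.8 CPM, Plekhh1 at 75.7 ± 7.45 and 36.6 ± 4.96 CPM, the netrin receptor gene Unc5b at 76.3 ± 9.93 and 36.2 ± 7.40 CPM, Chn2 at 52.7 ± 9.39 and 26.2 ± 1.59 CPM, and Dock9 at 127 ± 8.98 and 76.8 ± 5.67 CPM. Adgrb1, Slc12a2 and Mal completed the 10. Plekhh1, Tspan2 and Chn2 have exons that overlap a gene on the opposite strand and are uncertain. Mal is itself a mature oligodendrocyte marker, and the cells that the reads of these 10 genes came from were not told apart. Whether the lower values of the others are separate from those of the oligodendrocyte markers was not tested.

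**Figure D4:**
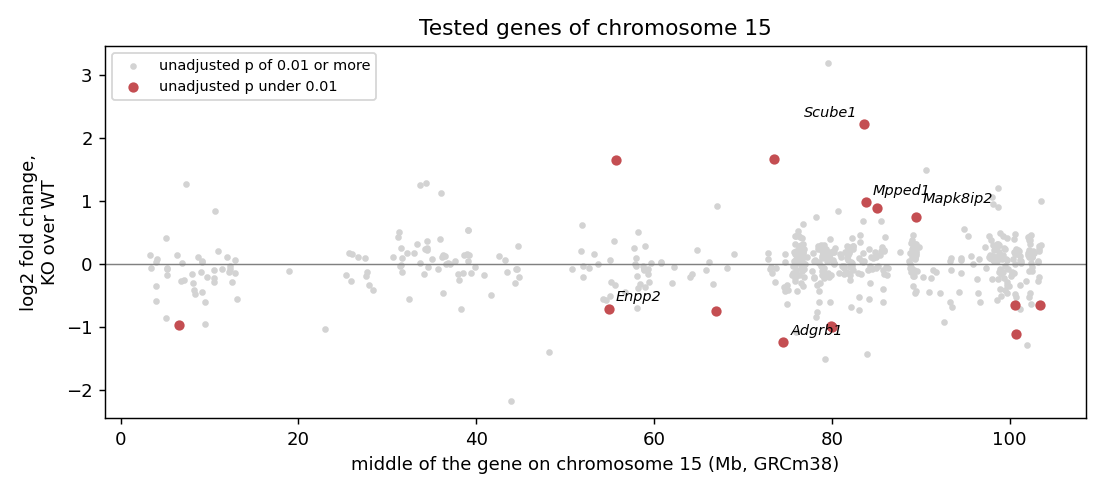
Log2 fold change of KO over WT for the tested genes of chromosome 15 by the middle of each gene in Mb (GRCm38), with red for an unadjusted p under 0.01. Scube1 stands at 2.23, Mpped1 at 0.99 and Adgrb1 at -1.24.

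The libraries also differed in a trend with GC content and gene length that only partly followed the genotype. Over genes, the KO over WT log2 fold change correlated with GC content at 0.291 and with log2 length at -0.253 (Spearman). GC-rich genes were relatively high in WT replicate 2 and KO replicates 1 and 2 (Spearman correlation with GC 0.057, 0.388 and 0.355). They were relatively low in WT replicates 1 and 3 and KO replicate 3 (-0.160, -0.334 and -0.394). Within the first set the KO minus WT difference in log2 CPM was -1.29 for Adgrb1 and -0.97 for the mean of the mature oligodendrocyte markers, and within the second -1.39 and -0.50. For oxidative phosphorylation it was 0.14 and 0.13, for ribosomal proteins 0.10 and 0.16, for oligodendrocyte precursor markers -0.42 and -0.45, for microglia markers -0.40 and -0.44, for astrocyte identity 0.31 and 0.11, for interferon genes -0.11 and 0.78, and for Gfap 1.03 and 0.22. In each set 1 genotype has a single library. Over both sets, with the set as a batch term, Adgrb1 was at -1.34 (edgeR adjusted p = 0.000160 over all genes tested) and Gfap at 0.65 (edgeR adjusted p = 0.154 over the 8 fixed genes alone), and 10 lists were higher and 3 lower with camera.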

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

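The correction for GC content and length, the batch term, the surrogate variable, the bias-adjusted quasi-likelihood and the dispersion without robust steps were chosen after seeing the data. Adgrb1 was lower in KO under every alternative run, from -1.39 with 1 surrogate variable to -1.13 without KO replicate 3, and from -1.35 to -1.13 over the fits that left out a library. Its adjusted p over all genes passed 0.05 with no low-count filter (-1.24), DESeq2 (-1.24), limma voom with quality weights (-1.19), the GC and length trend removed (-1.29), the side of that trend as a batch term (-1.34), 1 surrogate variable (-1.39) and without KO replicate 3 (-1.13), and ranged from 2.63e-09 with DESeq2 to 0.544 without KO replicate 2. The counts of genes higher and lower were 0 and 0 with RLE, total counts, the filter of 1 CPM and the bias-adjusted quasi-likelihood. The fold change of at least 2 (0 and 0) only narrows the 0 calls of the main fit, so its outcome was fixed in advance. The dispersion without robust steps (0 and 0) moved none of the values reported here and says nothing about stability. The counts higher and lower were 2 and 4 with no low-count filter, 17 and 62 with DESeq2 and 2 and 6 with limma voom. They were 3 and 12 with the GC and length trend removed, 14 and 74 with its side as a batch term, and 28 and 65 with 1 surrogate variable. Over the fits that left out a library they ranged from 0 to 4 and from 0 to 27, with 1 lower without WT replicate 1 and 4 and 27 without KO replicate 3. The cause was not tested. The labels do not say that the replicate numbers pair the libraries. The same-numbered libraries' deviations correlated at 0.09, 0.15 and 0.28, which was judged too low to pair them in the main fit. Still, 6 of 6 libraries correlated best with their own number, a hint from the data and not the design. For KO replicate 1 this was nearly a tie, at 0.0873 with WT replicate 1 and 0.0869 with WT replicate 2. Whether the numbers mark pairs stays undecided. The share of counts from Rn45s, a ribosomal RNA precursor, also lay close within each number, at 0.821% in WT and 0.821% in KO for replicate 1, 0.535% and 0.566% for replicate 2, and 0.328% and 0.311% for replicate 3. With the replicate number as a block, 7 genes were higher and 37 lower, and Adgrb1 was at -1.25 (adjusted p = 0.0143). Scube1, Gm5512, Sfrp5, Adgrb1 and Plekhh1 were called in the same direction by the block, DESeq2, the fit without KO replicate 3, the GC and length correction and the batch term. Of 39 lists, 0 were higher and 0 lower with an estimated correlation and 0 and 0 with fry. Lists higher numbered 4 with limma voom and 13 with 1 surrogate variable, and from 4 (without KO replicate 3) to 11 over the fits that left out a library. Lists lower ranged there from 3 to 7, with 7 without WT replicate 1. Some named genes near 0 that did not pass changed sign. Adgrb3 was at -0.029 with total counts, -0.022 with limma voom and -0.027 to 0.14 over the fits that left out a library (below 0 without WT replicate 1 or KO replicate 3), and Aqp4 at -0.0029, -0.19 and -0.24 to 0.24 (below 0 without WT replicate 2 or KO replicate 3). Slc1a2 was at 0.14 with the trend removed, 0.074 with the batch term, 0.066 with 1 surrogate variable and -0.19 to 0.095 when a library was left out (above 0 without WT replicate 1 or KO replicate 2), Mobp at -0.13 (without WT replicate 3) to 0.35 and Mertk at -0.27 to 0.017 (without KO replicate 3). All other values of the named genes kept their direction in these fits. Within the libraries where GC-rich genes were low, Megf10 and Sox10 also changed sign, with KO minus WT differences of 0.020 and 0.015 in log2 CPM. At this depth and spread a biological coefficient of variation of 28.0% left changes of 1.5-fold mostly undetected in simulation.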

Other observations

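All tests in this part were chosen after the values were seen, apart from the lists, which were fixed before the data were examined. Several lists that the report does not describe stood apart without passing. Erythroid markers (5 tested) were all below 0 in KO with a median log2 fold change of -1.31 (camera adjusted p = 0.0758), and WT replicate 3 stood highest for them. Extracellular matrix genes (35 tested) had a median of 0.26 (adjusted p = 0.0580), Wnt targets and components (20 tested) 0.22 (0.0722) and choroid plexus markers (6 tested) 0.92 (0.0860), a list in which Enpp2 fell from 471 ± 35.3 to 289 ± 85.3 CPM when adjusted over the list alone while 4 of the 6 genes were above 0. WT replicate 1 stood apart as the lowest for the choroid plexus list, with a mean deviation of -1.88 on the log2 scale against -0.003 and 0.18 in WT replicates 2 and 3 and 0.18 to 0.88 in KO, and for extracellular matrix and Wnt genes KO replicate 1 lay within the range of the WT libraries. In the lipid export and storage list (20 genes, median 0.12, adjusted p = 0.0902) Abcg1, a cholesterol exporter, fell from 58.0 ± 2.92 to 35.4 ± 2.60 CPM when adjusted over the list alone. Elavl3 fell from 103 ± 0.43 to 67.9 ± 6.54 CPM among neuron markers, a list with a median of 0.04 (adjusted p = 0.386), and Notch3 rose from 30.1 ± 2.39 to 49.5 ± 8.63 CPM among pericyte and smooth muscle markers, a list with a median of -0.37 (adjusted p = 0.338). Lost with single libraries were Abcg1 without WT replicate 3 or KO replicate 2, Enpp2 without WT replicate 1, WT replicate 2, KO replicate 1 or KO replicate 2, and Elavl3 and Notch3 in 5 of the 6 such fits, all but that without KO replicate 3. The pan-reactive, A1-type and A2-type astrocyte lists, complement and opsonins, synapse-regulating factors, lysosome and autophagy, p53 targets and angiogenesis regulators did not pass, with camera adjusted p of 0.338, 0.526, 0.248, 0.805, 0.386, 0.0902, 0.802 and 0.386.

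The first pattern is the low level of oligodendrocyte genes in KO. The 13 mature markers other than Mbp and Mobp had a median log2 fold change of -0.9996, and with the GC and length trend of the libraries removed it was -1.02, which argues against that trend as the source. Mbp and Mobp lay above the median of the other 13 by at least 4.18 standard errors, and by at least 4.31 with the trend removed, so removing it did not bring them nearer to the rest. A lower share of oligodendrocyte lineage cells in the KO cultures stays open for all 15 markers. The gap of Mbp and Mobp does not decide on it, because these 2 genes were picked for lying above the rest, Mobp was at -0.13 without WT replicate 3, and reads from other cells or stages were not measured apart. The lineage regulators Sox10, Olig1 and Olig2 had a median of -0.48, below 0 but nearer to it than that of the 13, which themselves ranged from -1.33 to -0.20. Lower transcription of myelin genes within cells, an effect of the genotype, stays open too and was not tested.

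The second pattern is that Scube1, Mpped1 and Mapk8ip2, all among the 10 higher genes of smallest p, lie within 20 Mb of Adgrb1 on chromosome 15. A candidate explanation is flanking sequence of another strain carried along with the targeted allele. Leaving out Adgrb1 itself, 10 of 307 tested genes within that distance had an unadjusted p under 0.01, against 212 of 13704 elsewhere (Fisher's exact test, two-sided p = 0.0317). But without the 3 genes that prompted the test the odds ratio was 1.4999, with 95% limits of 0.59 and 3.18. The first count holds the genes that prompted it. Leaving them out lowers the second by construction, as no gene elsewhere was left out. Neither count decides, so flanking sequence and an effect of losing ADGRB1 cannot be told apart here. The GC and length trend does not account for the 3 genes, as the smallest of their log2 fold changes was 0.70 with the trend removed.

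The third pattern is the higher level of oxidative phosphorylation and ribosomal protein genes in KO. The 78 genes had a median log2 fold change of 0.26, and 68.4% of it was left with the GC and length trend removed. The genotypes overlapped, with the lowest KO library minus the highest WT library at -0.28 on the log2 scale, and an exact two-sided permutation test of the library means gave p = 0.2, where 0.1 is the smallest possible. A level shared by these genes that varies from library to library therefore stays open as an account of the pattern. With the GC and length trend removed the median fell to 0.18, so part of the difference went with that trend. By that correction 68.4% was left, and the genotypes still overlapped. The lowest KO library minus the highest WT library was then at -0.19 on the log2 scale. Within the 2 sides of the trend the KO minus WT difference was smaller than over all 6 libraries. It was 0.14 and 0.13 for oxidative phosphorylation (mean log2 fold change 0.26) and 0.10 and 0.16 for ribosomal proteins (mean 0.28). How much of the difference goes with the trend is therefore not settled. A biological effect of the genotype was not tested apart from the shared level and the trend.

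The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. With edgeR the real split called 0 genes at an adjusted p of 0.05, a count that every split reaches, and the highest other called 1270 (452 and 818 in the 2 directions). At an unadjusted p under 0.05 the real split gave 871 genes, 2 of the 10 splits gave as many and the highest other gave 3614. For lists the real split called 11, 3 of the 10 splits called as many and the highest other called 13. No split called fewer than 4, so camera at the preset correlation called lists also where the groups mixed the genotypes. The split with 1270 genes set WT replicates 1 and 3 and KO replicate 3 against the other 3 libraries, the sides of the GC and length trend, and points to a structure of the libraries that crosses the genotype. With the side as a batch term, 14 genes were higher and 74 lower in KO.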
